A study of Mus musculus with 16 samples.

How the data were processed

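White adipose tissue RNA of 16 mouse samples was hybridized to Affymetrix whole-genome mouse arrays, 4 for each combination of genotype and diet. The fat depot is not given in the sources used here. RNA was extracted with Trizol and columns and 5 ug per sample was labelled, per the labels' protocols. The deposited values are log2 expression per probe set made by the authors with GCRMA 2.20.0 in R 2.11.1, per the submitters' processing notes. Filters and any handling of batches before deposit are not given in the sources used here. The values ran from 0.594 to 14.2, and no arrays held identical values.

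Of 45037 probe sets, 34945 carried 1 gene symbol, 932 several and 9160 none in the probe table. The gene identifiers of 34741 were found in the reference gene table, and 0 symbols needed updating. Each of the 18193 genes was represented by its brightest probe set with 1 symbol, and 9010 genes had more than 1. Genes with a log2 value of 4 or more in at least 4 arrays were tested, and 6115 were filtered out. At the low end of the scale a fold change depends on the background correction, so where every array of the lower group lay under a log2 of 4, the change with values floored at 4 was computed as well.

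Groups were taken from the labels. A linear model with 1 mean per group was fitted to the 16 arrays with limma 3.58.1 in R 4.3.3, with moderated two-sided tests (12 residual and 3.84 prior degrees of freedom). The comparisons were diet within each genotype, genotype within each diet and the interaction. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. The tests, the alternatives and the gene lists were chosen before the data were examined, except where stated. A replicate number did not pair the samples: over 24 pairs of same-numbered arrays the correlation of deviations from the group means ran from -0.321 to 0.199, with 5 over 0.1.

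The 29 gene lists held 512 entries. Of these, 470 were matched as written, 2 by an older symbol, and 40 were not in the table of probe sets with 1 gene; 425 entries were tested. The lists covered sirtuins and NAD, adipocytes, fat mass growth, fatty acid synthesis, cholesterol synthesis, lipolysis and oxidation, the respiratory chain, brown and beige fat, insulin and glucose, macrophages, lipid-loaded macrophages, cytokines, caspases and the inflammasome, interferon response, lymphocytes, neutrophils and mast cells, matrix, progenitors, endothelium, muscle, mesothelium, mammary epithelium, epididymal epithelium, erythroid cells, endoplasmic reticulum stress, the clock, the cell cycle, immediate early genes and sex-linked genes. Epididymal epithelium had 0 tested genes, which left 28. Lists were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the 28 lists within a comparison, and again with the correlation estimated from the data. Members were also counted with p adjusted over the list alone.

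For each pairwise comparison the genes named were the 10 with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, and up to 4 members with the smallest p from each list with a call or with members past the threshold. Of these list members, not every one is printed. Sirt1 was named throughout, and for the interaction the 5 genes with the smallest p in each direction. Of the calls shared by diet in wild type and knockout on the low fat diet, the 10 with the largest mean change were named. Symbols of provisional genes were counted and not named, and made up 229, 163, 122, 76 and 73 of the calls for diet in wild type, diet in knockout, knockout on the low fat diet, knockout on the high fat diet and the interaction.

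Alternatives changed the filter, the floor, the samples fitted, the variance model, array weights, scaling, the unit tested, the probe sets of a gene, the threshold, the control arrays and the inter-gene correlation, added the replicate number as a block, and left out each array in turn. Overlap of comparisons that share control arrays was set against 100 simulations of unchanged groups. The pipeline was tested on simulated data with 200 changed genes among 12078. For diet in wild type it called 156 with 12 false and recovered 43.3%, 83.6% and 89.4% of changes of 1.5, 2 and 4-fold. For knockout on the low fat diet it called 154 with 6 false and recovered 41.8%, 85.1% and 95.5%. For the interaction it called 95 with 3 false and recovered 2.99%, 44.8% and 90.9%. No call had the wrong sign, a list of 20 genes moved by 0.5 was called, and 0 of 20 unmoved lists were. The simulated genes varied independently of each other, so this does not test the calls of lists whose genes are correlated.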

Results

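White adipose tissue of C57BL6/J mice was profiled on 16 microarrays in 4 groups of 4, with 1 tissue sample per array. The groups crossed genotype with diet. Wild-type mice carried no Cre transgene, and knockout mice lacked SIRT1, an NAD-dependent protein deacetylase, through a Cre recombinase driven by the promoter of the fatty acid binding protein FABP4, which is active in adipocytes. The arrays do not show in which cells of the tissue Sirt1 was lost. Each genotype was fed a low fat or a high fat diet for 8 weeks from 4 weeks of age, and fat was taken at 12 weeks of age. No group carried the Cre transgene with intact Sirt1, so that the comparison of knockout with wild type includes the transgene. The values were log2 expression per probe set, and their median over all probe sets lay between 4.34 and 4.46 in the 16 arrays. A gene was tested if its brightest probe set reached a log2 value of 4 in at least 4 arrays, which kept 12078 of 18193 genes. Arrays of the same group correlated across probe sets with r between 0.987 and 0.996. The number of arrays, 4 in each group, limits the precision of every value that follows. The labels do not say whether replicates came from separate mice, so the p-values measure the spread between these samples. The genes given as the largest rises and falls were taken from those past the threshold whose groups did not overlap. All fold changes are differences of means of 4 against 4 arrays on the log2 scale, given with their standard error (SE), and adjusted p-values come from limma with Benjamini-Hochberg adjustment over the genes tested.

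The first principal component held 50.7% of the variance and ordered the groups. Its mean ± SD was -50.8 ± 3.51 in wild-type fat on the low fat diet, -12.2 ± 6.68 in knockout fat on the low fat diet, 14.5 ± 8.91 in wild-type fat on the high fat diet and 48.5 ± 5.05 in knockout fat on the high fat diet (n = 4 each).

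**Figure D1:**
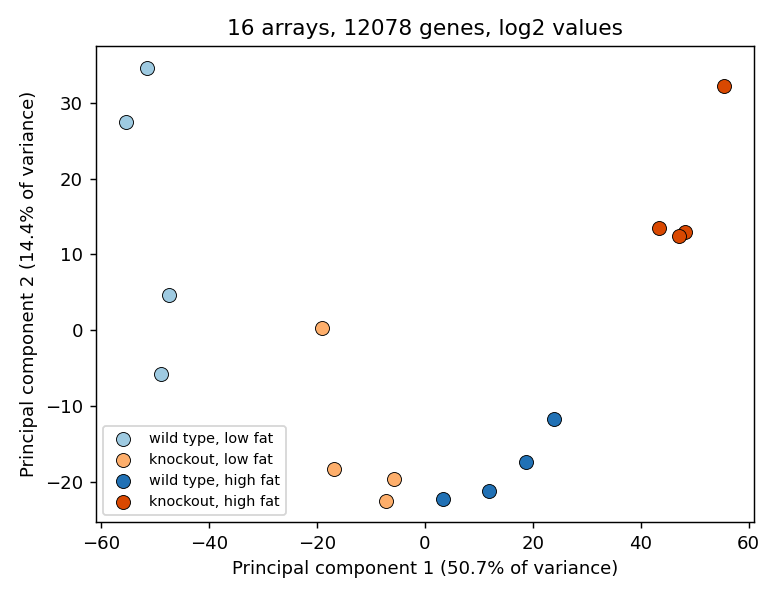
Scores of the 16 arrays on the first (50.7% of the variance) and second (14.4%) principal components of the log2 values of 12078 genes, with 1 point per array and 1 colour per group. Along the first component the groups run from wild type on the low fat diet through knockout on the low fat diet and wild type on the high fat diet to knockout on the high fat diet.

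The targeted gene was examined first. Sirt1 was measured by 1 probe set, whose position relative to the deleted part of the gene is not given in the sources used here, so that its signal cannot check the genotype labels. Its log2 value was 9.43 ± 0.35 (SD, n = 4) in wild-type and 9.24 ± 0.22 in knockout fat on the low fat diet. On the high fat diet it was 8.97 ± 0.14 in wild-type and 8.74 ± 0.30 in knockout fat. Array by array, the values were 9.42, 9.88, 9.02 and 9.41 in wild type and 9.37, 9.21, 9.44 and 8.94 in knockout on the low fat diet. They were 8.85, 9.10, 9.08 and 8.85 in wild type and 8.30, 8.93, 8.81 and 8.93 in knockout on the high fat diet. The knockout groups differed from the wild types by -0.19 on the low fat diet (95% confidence interval -0.57 to 0.19, adjusted p = 0.498) and by -0.22 on the high fat diet (-0.60 to 0.16, adjusted p = 0.448), within the spread between arrays. With the high fat diet the Sirt1 signal fell by 0.50 in knockout fat (SE 0.18, adjusted p = 0.0489). In wild-type fat the difference was -0.46 (SE 0.18, adjusted p = 0.056). The call in knockout fat ended under 15 of the other settings tried. These include leaving out any of knockout low fat replicates 1 to 3 (adjusted p = 0.114, 0.0803 and 0.134) and knockout high fat replicate 1 (adjusted p = 0.166), 3 (0.074) or 4 (0.0517). It also ended with wild-type arrays left out (adjusted p = 0.0548 to 0.0595). The call was not made for wild-type fat, but was made without wild-type low fat replicate 3 (adjusted p = 0.017), knockout low fat replicate 4 (0.0494) or knockout high fat replicate 1 (0.0347). It was also made with each array centred on the median of the genes tested (-0.55, adjusted p = 0.0262), with quantile normalization (0.0401), with the mean of the probe sets of a gene (0.0484) and without 5 arrays with skeletal muscle transcripts (-0.72, adjusted p = 0.049). Those arrays, with Tnnt3 at a log2 of 8 or more, were left out as an alternative chosen after the data were seen. They were wild-type low fat replicates 3 and 4, knockout low fat replicate 2, wild-type high fat replicate 3 and knockout high fat replicate 4. The cut was not sharp, since the last had Tnnt3 at 8.20 and wild-type high fat replicate 4, which was kept, at 7.95. For calls lost without these arrays, muscle transcripts and the smaller number of arrays cannot be told apart. The interaction for Sirt1 was -0.03 (adjusted p = 0.945).

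The largest rises with the high fat diet in wild-type fat were of Tph2 by 6.34 ± 0.91, Sfrp5 by 5.01 ± 0.21, Ptchd4 by 4.97 ± 0.26, Mmp12 by 4.48 ± 0.59, Atp1a4 by 4.45 ± 0.29, Cdkl4 by 4.28 ± 0.24, Peg10 by 4.26 ± 0.81, Itgax by 4.18 ± 0.40, Rnase2a by 4.16 ± 0.53 and Klf14 by 3.91 ± 0.28. Among these, Sfrp5 encodes a secreted inhibitor of Wnt signalling, Mmp12 the metalloelastase of macrophages, Itgax the integrin CD11c of inflammatory macrophages and dendritic cells, and Tph2 an enzyme of serotonin synthesis. The 4 low fat values of Ptchd4 lay under a log2 of 4, and with values under 4 set to 4 its rise was 4.40. Tph2 was at 8.19 in wild-type low fat replicate 1 and between 2.63 and 3.10 in the other 3 arrays of that group. The largest falls were of Acot3 (-5.39 ± 0.27), Apoc3 (-4.76 ± 0.43), Rassf6 (-4.19 ± 0.40), Ptgds (-4.00 ± 0.44), Cidea (-3.95 ± 0.66), Cyp2f2 (-3.69 ± 0.63), Drd1 (-3.39 ± 0.20), Mycl (-3.35 ± 0.45), Nr4a3 (-3.31 ± 0.24) and Pon1 (-3.28 ± 0.40). Acot3 is a peroxisomal acyl-CoA thioesterase, Apoc3 an apolipoprotein of triglyceride-rich particles, Ptgds a prostaglandin D synthase, Cidea a lipid droplet protein of brown fat and Drd1 a dopamine receptor. With values floored at 4 the changes of Acot3, Ptgds and Drd1, whose high fat values all lay under that level, were -3.20, -3.04 and -2.35. The adjusted p-values of these 20 genes ran from 1.1e-09 for Sfrp5 to 0.000783 for Peg10.

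In the gene lists fixed before the data were examined, genes tied to the growth of fat mass rose in wild-type fat on the high fat diet. Of 11 tested, 10 rose, among them Sfrp5, Mest by 3.35 ± 0.17 and Lep, the gene of the satiety hormone leptin, by 1.49 ± 0.17, and none fell (camera adjusted p = 2.2e-06, or adjusted p = 0.176 with an estimated correlation between genes). Collagens and matrix-remodelling genes rose as well, with 22 of 26 past the threshold and none down (camera adjusted p = 8.82e-11, adjusted p = 0.176 with an estimated correlation). Col15a1 rose by 3.58 ± 0.22 and Col6a1, a chain of the collagen VI around adipocytes, by 1.34 ± 0.11. Macrophage markers rose in 18 of 23 genes (camera adjusted p = 2.63e-07, adjusted p = 0.26 with an estimated correlation), with Clec7a up by 1.10 ± 0.14. Genes of lipid-loaded macrophages rose in 13 of 15 (camera adjusted p = 1.41e-05, adjusted p = 0.342 with an estimated correlation), with the cathepsin gene Ctsk up by 1.53 ± 0.22. Cell cycle genes rose in 20 of 22 (camera adjusted p = 1.05e-10, adjusted p = 0.214 with an estimated correlation), among them Aurkb, a mitotic kinase gene, by 2.28 ± 0.20 and Rrm2, for a subunit of ribonucleotide reductase, by 1.88 ± 0.24. Cytokines, chemokines and NF-kB targets rose in 11 of 18 and fell in 1 (camera adjusted p = 0.000273, adjusted p = 0.214 with an estimated correlation), with the acute phase gene Saa3 up by 1.89 ± 0.29. T, B and NK cell markers rose in 8 of 15 (camera adjusted p = 0.00221, adjusted p = 0.358 with an estimated correlation), with the granzyme gene Gzma up by 2.33 ± 0.39. Caspase and inflammasome genes rose in 7 of 14 (camera adjusted p = 0.0248, adjusted p = 0.343 with an estimated correlation), including the adaptor gene Pycard by 1.68 ± 0.24 and the sensor gene Naip2 by 1.61 ± 0.22. That call ended without wild-type low fat replicate 3 (adjusted p = 0.0683). Both it and the lymphocyte call ended without the 5 arrays with muscle transcripts (adjusted p = 0.0929 each). Interferon-response genes rose in 5 of 14 (camera adjusted p = 0.0248, adjusted p = 0.418 with an estimated correlation), a call lost without wild-type low fat replicate 4 (adjusted p = 0.0842) or high fat replicate 1 (adjusted p = 0.0504).

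With the high fat diet in wild-type fat, fatty acid and triglyceride synthesis fell in 14 of 24 genes and rose in 4 (camera adjusted p = 0.000112, adjusted p = 0.343 with an estimated correlation). Acacb, an acetyl-CoA carboxylase, fell by 2.28 ± 0.26 and Mlxipl, the carbohydrate-responsive factor ChREBP, by 1.55 ± 0.18. Lipolysis and fatty acid oxidation fell in 13 of 22 genes and rose in 1 (camera adjusted p = 5.37e-05, adjusted p = 0.343 with an estimated correlation), with the nuclear receptor gene Ppara down by 2.31 ± 0.31 and Ehhadh, of peroxisomal oxidation, by 1.34 ± 0.19. Brown and beige markers fell in 6 of 10 (camera adjusted p = 0.00169, adjusted p = 0.343 with an estimated correlation), among them Cidea, Ucp1, the uncoupling protein of heat-producing fat, by 3.65 ± 0.81 and Cox8b by 1.65 ± 0.34. Genes of the citric acid cycle and respiratory chain fell in 8 of 31, with none up (camera adjusted p = 0.000273, adjusted p = 0.416 with an estimated correlation). Clock genes fell in 7 of 15 (camera adjusted p = 0.00169, adjusted p = 0.214 with an estimated correlation), among them Nr1d1 by 1.98 ± 0.26 and Per1 by 1.34 ± 0.18. The time of day of tissue collection is not given in the sources used here. Mature adipocyte genes fell in 4 of 19 and rose in 2 (camera adjusted p = 0.045, adjusted p = 0.468 with an estimated correlation), with Pparg, the master regulator of adipocytes, down by 0.98 ± 0.15. That call ended when any of wild-type low fat replicates 2, 3 and 4 (adjusted p = 0.0604, 0.0741 and 0.0656) or wild-type high fat replicates 1 and 4 (adjusted p = 0.0506 and 0.0854) was left out, and without the 5 arrays with muscle transcripts (0.0929). The insulin and glucose list (2 up and 6 down of 22, camera adjusted p = 0.0972) and the sirtuin and NAD list (2 up and 4 down of 17, camera adjusted p = 0.134) were not called. The insulin receptor gene Insr fell by 1.19 ± 0.13 and Nampt, the NAD salvage enzyme gene, by 0.73 ± 0.19. The immediate early gene Egr2 rose by 3.44 ± 0.37, in a list that was not called (6 up of 15, camera adjusted p = 0.0679).

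In all, 4304 of 12078 genes changed with diet in wild-type fat, 2472 up and 1832 down, of which 893 rose and 364 fell at least 2-fold. In 30.8% of all genes tested the 4 arrays of one diet all lay above the 4 of the other, where chance gives 2.86%. The count was 2567 without the 5 arrays with muscle transcripts. With each array centred on the median of the genes tested the calls were 2050 up and 2552 down, and with quantile normalization 2062 up and 2539 down. Adjusted over the list alone, the rises numbered 10 for fat mass growth, 22 for matrix, 19 for macrophages, 13 for lipid-loaded macrophages and 20 for the cell cycle. On the same basis the falls numbered 15 for fatty acid synthesis, 13 for lipolysis and oxidation, 7 for brown and beige markers, 4 for the respiratory chain and 7 for the clock.

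**Figure D2:**
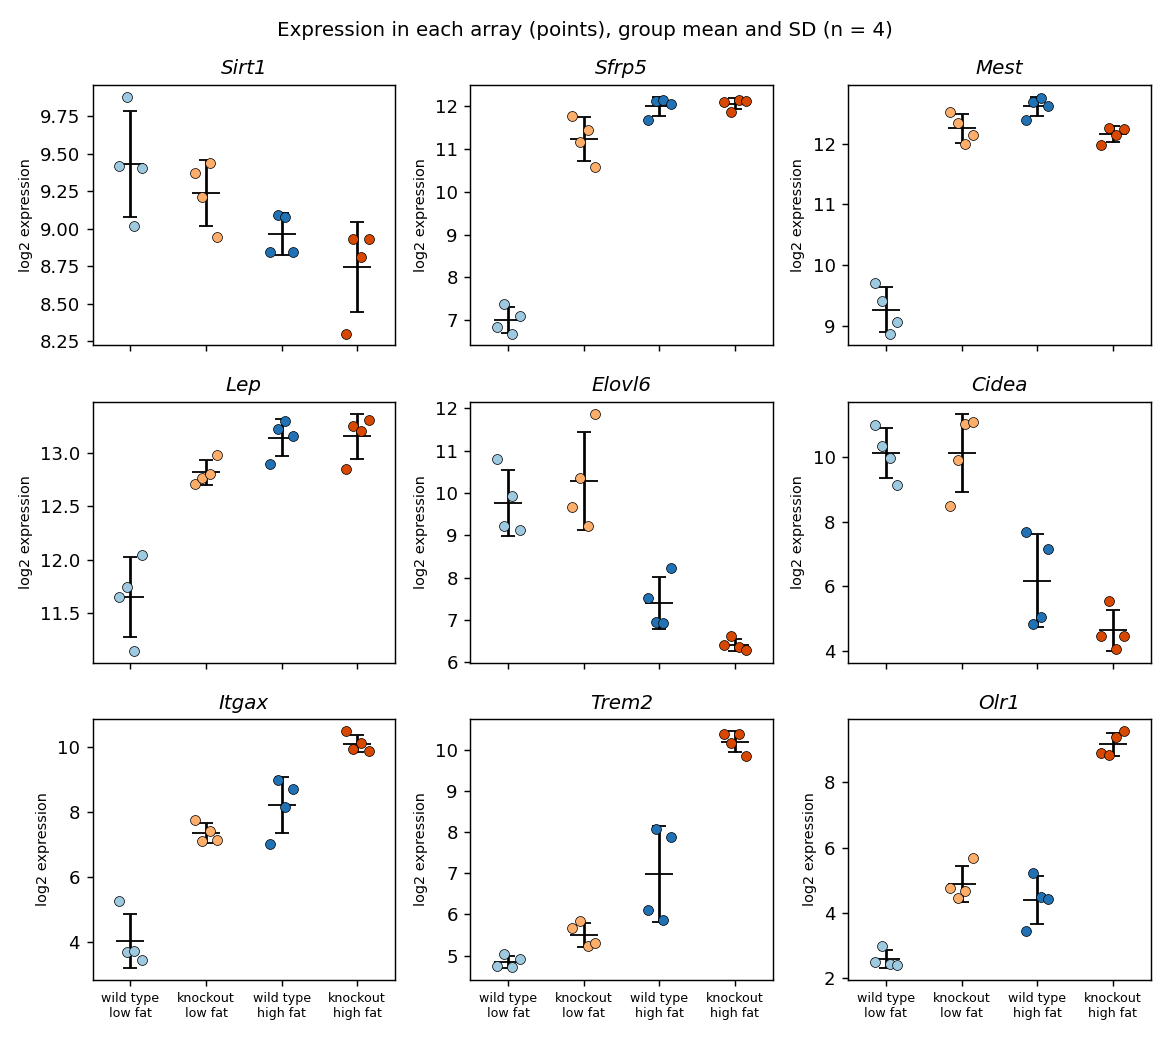
Log2 expression of 9 genes in each of the 16 arrays (points), by group, with the group mean (horizontal line) and SD (bars, n = 4). Sfrp5, Mest and Lep were lower in wild type on the low fat diet than in the other 3 groups, Elovl6 and Cidea were lower in both high fat groups, and Itgax, Trem2 and Olr1 were highest in knockout fat on the high fat diet.

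The same diet comparison in knockout fat gave a partly different picture. The largest rises were of Gpr50 by 8.40 ± 0.74, S100a7l2 by 5.46 ± 0.41, Tph2 by 4.96 ± 0.91, Trem2 by 4.69 ± 0.39, Il1rn by 4.63 ± 0.58, Shisa9 by 4.56 ± 0.50, Olr1 by 4.30 ± 0.32, Lcn2 by 4.28 ± 0.38, Rnf128 by 4.23 ± 0.78 and Ubd by 4.21 ± 0.48. Gpr50 encodes an orphan receptor related to melatonin receptors, Trem2 a lipid-sensing receptor of macrophages, Olr1 a receptor for oxidised LDL, Il1rn the antagonist of the interleukin-1 receptor and Lcn2 lipocalin 2. With values floored at 4, the rises of Gpr50, S100a7l2 and Shisa9, whose low fat values all lay under that level, were 6.54, 3.27 and 2.79. The largest falls were of Cidea (-5.50 ± 0.66), Ucp1 (-4.44 ± 0.81), Elovl6 (-3.86 ± 0.48), Cldn1 (-3.71 ± 0.40), Mpzl2 (-3.65 ± 0.58), Orm3 (-3.48 ± 0.29), Spock3 (-3.28 ± 0.71), Acsm3 (-3.02 ± 0.27), Pon1 (-3.01 ± 0.40) and Adgrg2 (-2.97 ± 0.24). Elovl6 is a fatty acid elongase and Cldn1 a claudin of tight junctions. The adjusted p-values of these 20 genes ran from 7.75e-07 for Olr1 to 0.00249 for Spock3.

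In knockout fat on the high fat diet, cell cycle genes rose in 21 of 22 (camera adjusted p = 1.15e-18, adjusted p = 0.161 with an estimated correlation), among them Tk1 by 3.47 ± 0.31 and Bub1 by 2.96 ± 0.24, or by 1.73 floored at 4. Macrophage markers rose in 19 of 23 (camera adjusted p = 7.71e-11, adjusted p = 0.161 with an estimated correlation), with Fcgr1 up by 2.98 ± 0.31 and Clec7a by 1.97 ± 0.14. Genes of lipid-loaded macrophages rose in 13 of 15 (camera adjusted p = 1.73e-09, adjusted p = 0.161 with an estimated correlation), with Trem2, Slc37a2 by 4.15 ± 0.39 and Gpnmb by 3.32 ± 0.36. Cytokines and chemokines rose in 11 of 18 and fell in 2 (camera adjusted p = 0.000285, adjusted p = 0.161 with an estimated correlation), with the chemokine gene Ccl3 up by 4.02 ± 0.33, or by 3.23 floored at 4. Matrix genes rose in 12 of 26 (camera adjusted p = 0.000102, adjusted p = 0.271 with an estimated correlation), with the protease gene Mmp3 up by 2.01 ± 0.15 and its inhibitor gene Timp1 by 2.97 ± 0.38. Caspase and inflammasome genes rose in 7 of 14 and fell in 1 (camera adjusted p = 0.00507, adjusted p = 0.25 with an estimated correlation). These included Pycard by 2.00 ± 0.24 and Casp1 by 0.93 ± 0.14, and also Il1rn, which opposes interleukin-1. Cholesterol synthesis rose in 10 of 15 and fell in 1 (camera adjusted p = 0.000675, adjusted p = 0.25 with an estimated correlation), with Dhcr7 up by 1.01 ± 0.12 and Mvd by 0.96 ± 0.15.

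The falls in knockout fat covered brown and beige markers in 8 of 10 genes (camera adjusted p = 0.000144, adjusted p = 0.25 with an estimated correlation), fatty acid synthesis in 12 of 24 with 2 up (camera adjusted p = 0.00108, adjusted p = 0.454 with an estimated correlation) and clock genes in 9 of 15 with 3 up (camera adjusted p = 0.000626, adjusted p = 0.161 with an estimated correlation). Acaca, an acetyl-CoA carboxylase, fell by 1.71 ± 0.29, Hlf, a clock-controlled factor, by 2.61 ± 0.21 and Per3 by 1.27 ± 0.16. Mesothelial markers, of the layer that covers visceral fat pads, fell in 8 of 10 (camera adjusted p = 9.1e-05, adjusted p = 0.271 with an estimated correlation), with Lrrn4 down by 2.24 ± 0.38 and Upk3b by 1.59 ± 0.28. The insulin and glucose list had 9 of 22 genes down and 2 up (camera adjusted p = 0.0407, adjusted p = 0.39 with an estimated correlation), among them the glucose transporter gene Slc2a4 by 0.68 ± 0.19. That call ended without knockout low fat replicate 4 (adjusted p = 0.114) or high fat replicate 3 (adjusted p = 0.0568), or without the 5 arrays with muscle transcripts (0.0575). Mature adipocyte genes fell in 5 of 19 (camera adjusted p = 0.0299, adjusted p = 0.522 with an estimated correlation), among them Pck1, for an enzyme of glycerol synthesis, by 0.89 ± 0.11. The adipocyte call ended without knockout low fat replicate 4 (adjusted p = 0.0966) or high fat replicate 1 (adjusted p = 0.0822). The respiratory chain (3 down of 31, camera adjusted p = 0.0161, adjusted p = 0.669 with an estimated correlation) lost its call without knockout low fat replicate 4 (adjusted p = 0.209). Lipolysis and oxidation (6 down of 22, camera adjusted p = 0.0407, adjusted p = 0.669 with an estimated correlation) lost it without knockout low fat replicate 3 (adjusted p = 0.0635) or 4 (0.251) or high fat replicate 1 (0.0822) or 3 (0.0613), and with the mean of the probe sets of a gene (0.0556). The fat mass list, called in wild-type fat, had 1 gene up and 2 down of 11 (camera adjusted p = 0.514), with Sfrp5 up by 0.82 ± 0.21. That rise was not called without the 5 arrays with muscle transcripts (adjusted p = 0.0745).

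In all, 3523 genes changed with diet in knockout fat, 1887 up and 1636 down, with 675 up and 387 down at least 2-fold. The groups did not overlap for 33.1% of the genes tested, against 2.86% by chance. With array weights in the fit, 5354 genes changed, and 2341 without the 5 arrays with muscle transcripts. Centring on the median turned the majority to 1730 up and 1929 down, and quantile normalization to 1814 up and 1886 down. Adjusted over the list alone, the rises numbered 21 for the cell cycle, 19 for macrophages, 13 for lipid-loaded macrophages, 12 for cytokines, 14 for matrix, 8 for inflammasome genes and 11 for cholesterol synthesis, and the falls 8 for brown and beige markers, 12 for fatty acid synthesis, 9 for the clock and 8 for mesothelium. On the same basis the falls numbered 0 for the respiratory chain, 5 for lipolysis and oxidation, 4 for mature adipocyte genes and 10 for insulin and glucose (2 up). The diet effects of the genotypes, which share no array, had r = 0.53 across 12078 genes, which are not independent replicates. Of the genes called, 1731 changed in the same direction in both genotypes, 1052 up and 679 down, and 132 in opposite directions, where independent lists would share 386.2 up and 248.2 down.

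**Figure D3:**
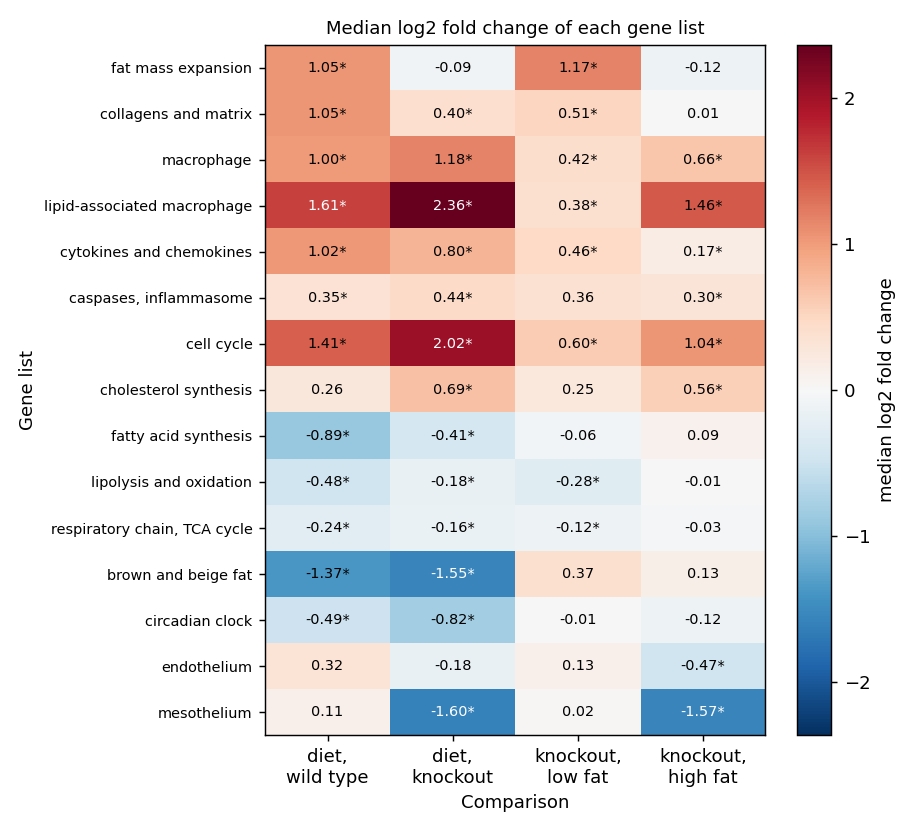
Median log2 fold change (colour and number) of 15 gene lists in the 4 pairwise comparisons, with an asterisk where camera with a preset correlation gave an adjusted p under 0.05; no list was called with an estimated correlation. The fat mass list stands at 1.05 with diet in wild type and 1.17 with knockout on the low fat diet, and near 0 in the other comparisons.

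On the low fat diet, the knockout was compared with wild type to ask whether loss of SIRT1 alone moves the genes that a high fat diet moves, a relation that the title of the series raises. Knockout fat had higher Ptchd4 (by 4.68 ± 0.26, or 4.11 floored at 4), Sfrp5 (4.24 ± 0.21), Tfr2 (3.82 ± 0.40), Atp1a4 (3.67 ± 0.29), Klf14 (3.61 ± 0.28), Plppr4 (3.59 ± 0.32), Ccn5 (3.41 ± 0.73), Bcat1 (3.40 ± 0.38), Mmp12 (3.36 ± 0.59) and Lipf (3.36 ± 0.30, or 1.41 floored at 4). Tfr2 encodes transferrin receptor 2, Bcat1 an aminotransferase of branched-chain amino acids and Ccn5 a secreted matricellular protein. The largest falls were of Acot3 (-4.49 ± 0.27, or -3.20 floored at 4), Apoc3 (-3.67 ± 0.43), Rassf6 (-3.39 ± 0.40), Nipal1 (-3.05 ± 0.54, or -1.77 floored at 4), Drd1 (-3.04 ± 0.20, or -2.35 floored at 4), Nr4a3 (-2.77 ± 0.24), Ptgds (-2.65 ± 0.44), Hs3st3b1 (-2.55 ± 0.28), Flvcr2 (-2.44 ± 0.28) and Mycl (-2.40 ± 0.45). The adjusted p-values of these 20 genes ran from 1.42e-08 for Sfrp5 to 0.0045 for Ccn5.

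The fat mass list rose in 10 of 11 genes in knockout fat on the low fat diet (camera adjusted p = 1.38e-08, adjusted p = 0.0748 with an estimated correlation), with Mest up by 2.99 ± 0.17 and Lep by 1.17 ± 0.17. Matrix genes rose in 13 of 26 (camera adjusted p = 6.57e-06, adjusted p = 0.607 with an estimated correlation), with Col15a1 up by 3.11 ± 0.22 and Col6a2 by 1.40 ± 0.17. Macrophage markers rose in 6 of 23 (camera adjusted p = 0.000504, adjusted p = 0.607 with an estimated correlation), with Adgre1, the gene of a macrophage surface receptor, up by 1.01 ± 0.21 and Ctss by 0.74 ± 0.17. Genes of lipid-loaded macrophages rose in 5 of 15 (camera adjusted p = 0.016, adjusted p = 0.607 with an estimated correlation), with Itgax up by 3.33 ± 0.40. Cell cycle genes rose in 7 of 22 (camera adjusted p = 0.000539, adjusted p = 0.607 with an estimated correlation), with Rrm2 up by 1.58 ± 0.24 and Aurkb by 1.11 ± 0.20. Lipolysis and oxidation fell in 6 of 22 and rose in 1 (camera adjusted p = 0.00379, adjusted p = 0.607 with an estimated correlation), with Ehhadh down by 1.10 ± 0.19 and Pnpla2, the gene of adipose triglyceride lipase, by 0.39 ± 0.09. Cytokines and chemokines (4 up of 18, camera adjusted p = 0.0384, adjusted p = 0.607 with an estimated correlation), with Saa3 up by 0.97 ± 0.29, lost the call without any 1 of 3 arrays. These were wild-type low fat replicate 3 (adjusted p = 0.0848) and knockout low fat replicates 1 and 2 (adjusted p = 0.117 and 0.0807). Lymphocyte markers (3 up of 15, camera adjusted p = 0.0384, adjusted p = 0.607 with an estimated correlation), with Gzma up by 1.78 ± 0.39 and Klrd1 by 1.29 ± 0.27, lost it without wild-type low fat replicate 3 (adjusted p = 0.0848) or 4 (0.134) or knockout low fat replicate 1 (0.172). Stromal progenitor markers (5 up of 13, camera adjusted p = 0.0384, adjusted p = 0.607 with an estimated correlation), with Thy1 up by 0.83 ± 0.19 and Cd34 by 0.70 ± 0.14, lost it without wild-type low fat replicate 1 (adjusted p = 0.0989) or 3 (0.0848) or knockout low fat replicate 1 (0.0578), 2 (0.0725) or 3 (0.0555). The respiratory chain list had no gene past the threshold (0 of 31, median -0.12, camera adjusted p = 0.0384, adjusted p = 0.669 with an estimated correlation). Its call ended without wild-type low fat replicate 1 (adjusted p = 0.0796) or 3 (0.101) or knockout low fat replicate 1 (0.16), 2 (0.0953) or 3 (0.0555). Fatty acid synthesis was not called (3 up and 7 down of 24, camera adjusted p = 0.341). Acacb fell by 1.25 ± 0.26 and Aacs, for an acetoacetyl-CoA synthetase, by 0.74 ± 0.13, while Scd2 rose by 1.06 ± 0.14 and Pnpla3 by 2.75 ± 0.41. Brown and beige markers (2 up and 1 down of 10, camera adjusted p = 0.475) and clock genes (1 up and 1 down of 15, camera adjusted p = 0.478) were not called. The insulin and glucose list (1 up and 3 down of 22, camera adjusted p = 0.351) and mature adipocyte genes (1 up and 2 down of 19, camera adjusted p = 0.0702) were not called. Among their members Insr fell by 0.84 ± 0.13, the insulin receptor substrate gene Irs2 by 0.90 ± 0.19 and Pparg by 0.72 ± 0.15. The rise of Saa3 was not called without wild-type low fat replicate 3 (adjusted p = 0.0839) or 4 (0.0798) or knockout low fat replicate 1 (0.0786), 2 (0.0829) or 3 (0.0616). It was 0.24 (adjusted p = 0.623) without the 5 arrays with muscle transcripts. Leaving out those 5 arrays also ended the calls of Adgre1 (adjusted p = 0.152), Ctss (0.104), Aurkb (0.107), Pnpla2 (0.199), Acacb (0.141), Klrd1 (0.152), Thy1 (0.0562), Cd34 (0.114) and Pparg (0.0991). Among the lists it ended those of lipid-loaded macrophages (adjusted p = 0.0736), the cell cycle (0.163), lipolysis and oxidation (0.0736), cytokines (0.238), lymphocytes (0.546), progenitors (0.161) and the respiratory chain (0.17). With values floored at 4 the cytokine (adjusted p = 0.0699), lymphocyte (0.0613) and respiratory chain (0.0514) lists were not called. The progenitor list was not called with the mean of the probe sets of a gene (adjusted p = 0.0907).

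In all, 2284 genes differed between knockout and wild type on the low fat diet, 1410 higher and 874 lower in knockout, with 387 and 147 of them at least 2-fold. The groups did not overlap for 17.9% of the genes tested, against 2.86% by chance. The count was 1426 without knockout low fat replicate 1, 1515 without knockout low fat replicate 2 and 1292 when only the 8 arrays compared were fitted. Without the 5 arrays with muscle transcripts it was 845. Centred on the median of the genes tested the calls were 1151 higher and 1274 lower, and with quantile normalization 1123 higher and 1281 lower. Adjusted over the list alone, the rises numbered 10 for fat mass growth, 14 for matrix, 11 for macrophages, 6 for lipid-loaded macrophages, 13 for the cell cycle, 6 for cytokines, 5 for lymphocytes and 6 for progenitors, and the falls 6 for lipolysis and oxidation.

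The calls of the knockout on the low fat diet overlapped those of the high fat diet in wild-type fat. Of the 2284 genes called by knockout on the low fat diet, 1924 (84.2%) were also called by diet in wild type in the same direction, 1187 up and 737 down, and 3 in the opposite direction. The 10 genes with the largest mean change were Ptchd4, Acot3, Tph2, Sfrp5, Apoc3, Atp1a4, Mmp12, Rassf6, Klf14 and Itgax. For Tph2 the difference on the low fat diet was 3.24 ± 0.91 (adjusted p = 0.021). It was not called without wild-type low fat replicate 3 (adjusted p = 0.0628) or 4 (0.0605) or knockout low fat replicate 1 (0.0734) or 2 (0.0577). The difference was 1.59 (adjusted p = 0.44) without the 5 arrays with muscle transcripts. The comparisons share the 4 wild-type low fat arrays. In 100 simulations of unchanged groups that shared simulated controls, a mean of 0.62 genes were called alike and at most 62. The simulated arrays were drawn with replacement from the deviations of all arrays from their group means. The real controls were not held fixed, and the same array could stand in the control and in a compared group. Independent lists of these sizes would share 288.6 genes up and 132.6 down. The log2 fold changes had r = 0.84 across 12078 genes, against a simulated mean of 0.50 (range -0.47 to 0.89), and a covariance of 0.28, against a simulated mean of 0.03 and a highest value of 0.10. The covariance exceeded the simulated mean by 0.25. With the 4 controls split 2 and 2, so that each comparison had its own, the mean over the 6 splits was r = 0.67 (0.62 to 0.78), a covariance of 0.25 (0.23 to 0.27) and 1014 genes called alike (818 to 1326), with 8.83 called in opposite directions (1 to 20). The number called alike in the full fit was 1264 without knockout low fat replicate 1, 1277 with a 1.5-fold minimum and 721 without the 5 arrays with muscle transcripts.

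**Figure D4:**
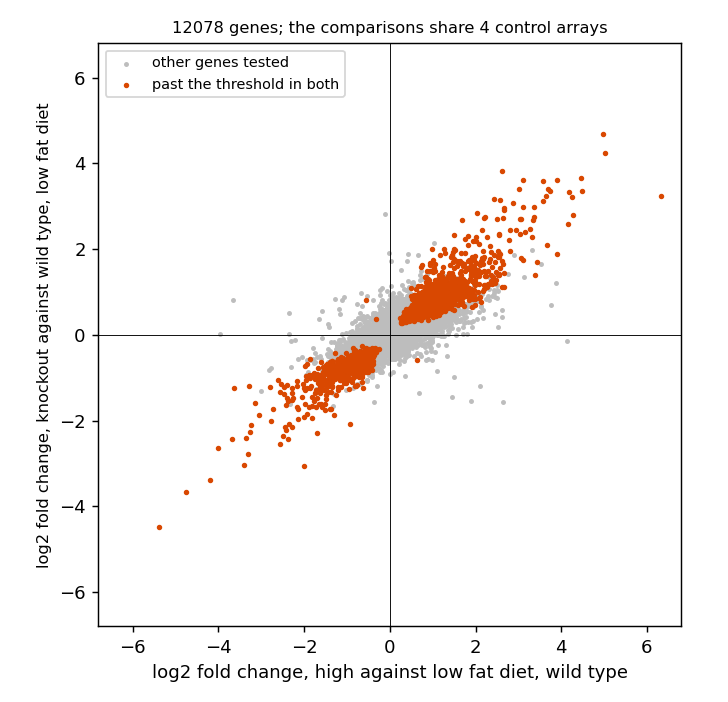
Log2 fold change of 12078 genes (1 point each) with the high fat diet in wild type (horizontal axis) against that of knockout over wild type on the low fat diet (vertical axis); genes past the threshold in both are coloured. The coloured points lie in the quadrants of like direction except for 3 genes, and r is 0.84, part of which comes from the 4 control arrays that both axes share.

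On the high fat diet, knockout fat had higher Olr1 (by 4.79 ± 0.32), S100a7l2 (4.47 ± 0.41, or 3.27 floored at 4), Gpr50 (4.11 ± 0.74), Lcn2 (4.07 ± 0.38), Hmga2 (3.34 ± 0.30), Shisa9 (3.28 ± 0.50), Trem2 (3.22 ± 0.39), Zranb3 (3.12 ± 0.34), Ccl3 (3.11 ± 0.33) and Nptx1 (3.07 ± 0.31, or 1.84 floored at 4). Hmga2 encodes a chromatin protein of growing cells. The largest falls were of Rnase2a (-4.29 ± 0.53, or -3.83 floored at 4), Mucl1 (-2.81 ± 0.32, or -1.12 floored at 4), Spock3 (-2.70 ± 0.71), Perp (-2.69 ± 0.83), Krt18 (-2.67 ± 0.82), Trp63 (-2.66 ± 0.72), Mpzl2 (-2.56 ± 0.58), Rab27b (-2.53 ± 0.76), Eci3 (-2.48 ± 0.24) and Celsr2 (-2.44 ± 0.24). Perp, Krt18, Trp63 and Rab27b are epithelial genes that stood at least 4-fold higher in wild-type high fat replicate 4 than in any of the other 15 arrays. Without that array the differences were -1.56 for Perp (adjusted p = 0.0473), -1.47 for Krt18 (0.0233), -1.63 for Trp63 (0.0104) and -1.62 for Rab27b (0.0771, not called), and -2.35 for Spock3 (0.0513, not called). They were -1.86 for Mpzl2 (adjusted p = 0.00987) and -2.37 for Celsr2 (8.8e-05). Without knockout high fat replicate 1 none of Perp, Krt18, Trp63, Rab27b and Spock3 was called (adjusted p = 0.112, 0.106, 0.0619, 0.12 and 0.0703). Without replicate 2 Perp and Krt18 were not (0.0744 and 0.0671), without replicate 3 Perp, Krt18, Trp63 and Rab27b were not (0.0545, 0.0541, 0.054 and 0.0663), and without replicate 4 Perp, Krt18 and Rab27b were not (0.0587, 0.0726 and 0.0551). Perp was also not called without wild-type high fat replicate 1 (adjusted p = 0.0577). Without a filter on low values Perp and Krt18 were not called (adjusted p = 0.0527 and 0.0524). With a mean-variance trend and robust fit Perp, Krt18 and Rab27b were not (0.0622, 0.0646 and 0.0563). Leaving out the 5 arrays with muscle transcripts ended the calls of Perp (adjusted p = 0.0679), Krt18 (0.112), Trp63 (0.0575) and Rab27b (0.0693). In the full fit the adjusted p-values of these 20 genes ran from 1.29e-06 for Olr1 to 0.038 for Perp.

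Cell cycle genes were higher in knockout fat on the high fat diet in 19 of 22 (camera adjusted p = 1.54e-13, adjusted p = 0.251 with an estimated correlation), with Tk1 up by 2.39 ± 0.31 and Bub1 by 2.12 ± 0.24. Macrophage markers were higher in 12 of 23 (camera adjusted p = 2.2e-08, adjusted p = 0.251 with an estimated correlation), with the scavenger receptor gene Msr1 up by 2.03 ± 0.28 and Clec7a by 1.45 ± 0.14. Genes of lipid-loaded macrophages were higher in 8 of 15 (camera adjusted p = 7.03e-08, adjusted p = 0.251 with an estimated correlation), with Ctsk up by 1.56 ± 0.22 and Cd5l by 1.46 ± 0.21. Cholesterol synthesis was higher in 6 of 15 and lower in 1 (camera adjusted p = 0.000298, adjusted p = 0.251 with an estimated correlation), with Nsdhl up by 1.00 ± 0.19 and Dhcr7 by 0.98 ± 0.12. Caspase and inflammasome genes were higher in 7 of 14 (camera adjusted p = 0.0115, adjusted p = 0.297 with an estimated correlation), with Pycard up by 1.18 ± 0.24 and Casp1 by 0.87 ± 0.14. Mesothelial markers were lower in 9 of 10 (camera adjusted p = 8.33e-07, adjusted p = 0.251 with an estimated correlation), with Gpm6a down by 1.64 ± 0.40 and Upk3b by 1.46 ± 0.28. Without wild-type high fat replicate 4 they were lower in 7 of 10 (camera adjusted p = 1.1e-06). Endothelial markers were lower in 5 of 12 (camera adjusted p = 0.000298, adjusted p = 0.251 with an estimated correlation), with Kdr, the VEGF receptor gene, down by 1.07 ± 0.17 and Tek by 0.53 ± 0.16. Tek was not called without wild-type high fat replicate 1 (adjusted p = 0.0561), 2 (0.067) or 3 (0.1) or knockout high fat replicate 1 (0.0951), or without the 5 arrays with muscle transcripts (0.134). Mature adipocyte genes were lower in 3 of 19 (camera adjusted p = 0.0285, adjusted p = 0.459 with an estimated correlation), with the retinol carrier gene Rbp4 down by 0.83 ± 0.15 and Retn, the resistin gene, by 0.56 ± 0.16. The list lost its call without wild-type high fat replicate 3 (adjusted p = 0.0677), knockout high fat replicate 1 (0.0846) or the 5 arrays with muscle transcripts (0.0585). Retn lost it without wild-type high fat replicate 2 (adjusted p = 0.073), 3 (0.082) or 4 (0.066) or knockout high fat replicate 1 (0.107) or 4 (0.054), or without those 5 arrays (0.167). Cytokines and chemokines were higher in 5 of 18 and lower in 1 (camera adjusted p = 0.0298, adjusted p = 0.459 with an estimated correlation), a call lost without knockout high fat replicate 4 (adjusted p = 0.0601) or those 5 arrays (0.095). The fat mass list (0 of 11, camera adjusted p = 0.091), matrix genes (3 up of 26, camera adjusted p = 0.948) and fatty acid synthesis (4 up and 1 down of 24, camera adjusted p = 0.764) were not called, though Pnpla3 was higher by 2.07 ± 0.41. In the insulin and glucose list, which was not called either (2 up and 4 down of 22, camera adjusted p = 0.115), Irs1 was lower by 1.09 ± 0.22.

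In all, 1818 genes differed between knockout and wild type on the high fat diet, 1036 higher and 782 lower in knockout, with 349 and 208 of them at least 2-fold. The groups did not overlap for 26.1% of the genes tested, against 2.86% by chance. The count was 1084 without knockout high fat replicate 1, 1204 without wild-type high fat replicate 3, 814 without the 5 arrays with muscle transcripts and 3424 with array weights. Adjusted over the list alone, the rises numbered 21 for the cell cycle, 15 for macrophages, 12 for lipid-loaded macrophages, 9 for cholesterol synthesis and 7 for inflammasome genes, and the falls 10 for mesothelium and 8 for endothelium. In lists that were not called, 4 of 11 fat mass genes were lower on that basis, and 7 of 22 insulin and glucose genes were lower and 3 higher. The genotype effects on the 2 diets, which share no array, had r = 0.16 across genes. Of the genes called, 361 changed in the same direction on both diets, 250 up and 111 down, and 121 in opposite directions, where independent lists would share 120.9 up and 56.6 down.

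The interaction tested whether the diet effect differed between genotypes. The interaction, diet effect in knockout minus that in wild type, was -3.45 ± 0.24 for Mest, -4.19 ± 0.30 for Sfrp5, -4.64 ± 0.36 for Ptchd4, -3.01 ± 0.25 for Abat, the GABA transaminase gene, and -4.46 ± 0.40 for Klf14. It was 3.33 ± 0.28 for Drd1, 4.30 ± 0.38 for Acot3, 2.30 ± 0.26 for Nrcam, 2.19 ± 0.26 for Npc1, the lysosomal cholesterol transporter gene, and 2.76 ± 0.34 for Nr4a3. The means of Drd1 and Acot3 lay under a log2 of 4 in every group but wild type on the low fat diet. With values floored at 4 their interactions were 2.35 and 3.20. Floored in the same way, that of Nrcam was 2.22 and that of Ptchd4 -4.08. The adjusted p-values of these 10 genes ran from 1.57e-06 for Mest to 0.000168 for Nr4a3. Mest stood at 9.26 ± 0.37 in wild type on the low fat diet and at 12.25 ± 0.24 in knockout on the low fat diet. On the high fat diet it stood at 12.62 ± 0.16 in wild type and 12.16 ± 0.13 in knockout (SD, n = 4).

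The fat mass list had a negative interaction in 8 of 11 genes (camera adjusted p = 1.47e-09, adjusted p = 0.0515 with an estimated correlation). Matrix genes had it in 8 of 26 with 1 positive (camera adjusted p = 0.001), progenitor markers in 4 of 13 (0.00335), endothelial markers in 1 of 12 (0.00375) and mesothelial markers in 3 of 10 (0.00145). Each of these 4 had an adjusted p = 0.653 with an estimated correlation. The mean of the mesothelial list was 9.81 in wild-type high fat replicate 4 and 8.11 to 8.53 in the other arrays of that group. Interferon-response genes had a negative interaction in 4 of 14 (camera adjusted p = 0.017, adjusted p = 0.676 with an estimated correlation), a call lost without wild-type low fat replicate 4 (adjusted p = 0.0641). Cell cycle genes had a positive interaction in 3 of 22 (camera adjusted p = 0.00375, adjusted p = 0.7 with an estimated correlation). Cholesterol synthesis (2 positive of 15, camera adjusted p = 0.0437, adjusted p = 0.684 with an estimated correlation) lost its call without any 1 of 10 arrays (adjusted p = 0.0502 to 0.128). Lipolysis and oxidation (2 positive of 22, camera adjusted p = 0.0388, adjusted p = 0.734 with an estimated correlation) lost it without any 1 of 7 (0.053 to 0.108). Lymphocyte markers (1 positive and 3 negative of 15, camera adjusted p = 0.0437, adjusted p = 0.7 with an estimated correlation) lost it without any 1 of 6 (0.0546 to 0.133). These 3 calls also ended without the 5 arrays with muscle transcripts (adjusted p = 0.077, 0.13 and 0.33). With values floored at 4 the cholesterol (adjusted p = 0.0594) and lymphocyte (0.073) calls ended. The cholesterol (0.182) and lipolysis (0.0551) calls ended with the mean of the probe sets of a gene.

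In all, 1569 genes had an interaction, 618 positive and 951 negative. The count was 2382 without wild-type low fat replicate 2, 424 without the 5 arrays with muscle transcripts, 2481 with array weights and 2495 at an adjusted p under 0.10. With arrays centred on the median of the genes tested 853 were positive and 868 negative, and with quantile normalization 989 and 885. Adjusted over the list alone, the negative interactions numbered 10 for fat mass, 13 for matrix, 8 for progenitors, 8 for endothelium and 6 for mesothelium, and the positive ones 3 for the cell cycle.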

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

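Of the tests in this part, those of shared control arrays, simulated shifts of the wild-type low fat arrays, macrophages, exchanged labels, mesothelium, swapped or scaled values, a strain segment as the source of most genes and low signal were chosen only after the result was seen.

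In a group of 4 arrays, 1 array was marked where its gap to the nearest other exceeded Dixon's 95% critical share of the range of the group. This held for 3 of 100 list means and 33 of 480 values of named genes, where chance marks about 1 in 20, or 5 and 24. In the wild-type low fat group these were the macrophage list (9.256), Flvcr2 (8.274), Itgax (5.253), Rnf128 (5.4), Tph2 (8.186) in replicate 1, and Cdkl4 (4.365), Insr (10.99), Olr1 (2.976) in replicate 2, and the mesothelial list (7.692), Upk3b (10.26) in replicate 3, and Mucl1 (4.299), Ucp1 (7.799) in replicate 4. In the knockout low fat group these were Msr1 (6.569), S100a7l2 (1.553) in replicate 3, and the fatty acid synthesis list (11.18), Hmga2 (5.031), Krt18 (9.018), Ptgds (6.288), Rbp4 (12.73) in replicate 4. In the wild-type high fat group these were Gpr50 (3.072), Retn (12.5), Sfrp5 (11.68) in replicate 1, and Aurkb (6.759) in replicate 2, and Pnpla3 (8.196) in replicate 3, and Krt18 (12.73), Nipal1 (6.204), Shisa9 (5.598), Trp63 (9.931) in replicate 4. In the knockout high fat group these were Egr2 (11.3), Irs1 (8.713), Nampt (8.685), Slc2a4 (9.798), Tek (9.204) in replicate 1, and Hlf (5.984), Lcn2 (10.09) in replicate 2, and Lipf (8.119) in replicate 4. Wild-type high fat replicate 4 had 4 of these.

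The diet effect differed between genotypes by the interaction test for 61 named genes and, at the preset correlation between genes, for 10 lists. The genes had been named for large changes or small p in the same arrays, so the selection raises their count. Of all genes tested, 12.99% had an interaction. With an estimated correlation none of the 10 lists was called (adjusted p = 0.0515 to 0.734), and the calls of cholesterol synthesis, lipolysis and lymphocytes ended without any 1 of 10, 7 and 6 arrays. The interaction, diet effect in knockout minus that in wild type, was positive for S100a7l2 (4.706), Apoc3 (4.331), Acot3 (4.304), Gpr50 (4.264), Drd1 (3.333), Shisa9 (3.306), Hmga2 (3.1), Lcn2 (2.998), Zranb3 (2.969), Nptx1 (2.92), Ccl3 (2.905), Nr4a3 (2.765), Trem2 (2.554), Ptgds (2.515), Olr1 (2.48), Nrcam (2.297), Npc1 (2.191), Rassf6 (2.113), Slc37a2 (1.977), Msr1 (1.81), Gpnmb (1.708), Fcgr1 (1.561), Tk1 (1.542), Bub1 (1.527), Hs3st3b1 (1.433), Mlxipl (1.013), Clec7a (0.866), Mmp3 (0.8095), Mvd (0.6972), Aacs (0.6807). It was negative for Rnase2a (-6.888), Peg10 (-5.672), Ptchd4 (-4.64), Klf14 (-4.463), Rab27b (-4.398), Sfrp5 (-4.188), Mucl1 (-3.543), Mest (-3.447), Spock3 (-3.242), Atp1a4 (-3.222), Abat (-3.008), Col15a1 (-2.939), Plppr4 (-2.809), Bcat1 (-2.419), Orm3 (-2.211), Eci3 (-2.151), Cdkl4 (-2.094), Gzma (-1.91), Gpm6a (-1.859), Lrrn4 (-1.796), Klrd1 (-1.72), Lipf (-1.64), Upk3b (-1.523), Col6a2 (-1.446), Hlf (-1.197), Lep (-1.154), Col6a1 (-1.152), Per3 (-0.9925), Thy1 (-0.9807), Cd34 (-0.941), Rbp4 (-0.7142). These gene values are not floored at 4, and all knockout low fat arrays of S100a7l2 lay under that level. Rab27b stood 3.181 higher in wild-type high fat replicate 4 than in any other array. The median interaction of the lists was -1.262 for fat mass, -0.5415 for matrix, -1.702 for mesothelium, -0.7912 for progenitors, -0.5912 for endothelium, -0.3822 for interferon response and -0.8565 for lymphocytes, and 0.3795 for the cell cycle, 0.2837 for cholesterol synthesis and 0.2756 for lipolysis and oxidation.

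Among genes that were not tested because they reached a log2 of 4 in too few arrays, the bladder lining genes Upk1a, Upk2 and Upk3a stood at 11.708, 10.644 and 11.022 in wild-type high fat replicate 4. They were singled out here after their values were seen. Their highest values in the other 15 arrays were 4.219, 3.808 and 4.107, and in wild-type fat on the low fat diet 2.829, 2.892 and 3.006.

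Knockout on the low fat diet moved genes in the direction in which the high fat diet moved them in wild type. The lowest covariance over the 6 splits of the controls was 0.2255, against a highest simulated value of 0.0955. That argued against errors of single shared control arrays, though the simulations drew arrays from all groups and did not hold the real controls fixed. For the fatty acid synthesis list, the lowest array with a low fat label lay 0.219 above the highest with a high fat label. Only if diet and not genotype lowers the list does this argue against exchanged wild-type high fat and knockout low fat labels. With exchanged labels the same gap would read as a genotype effect. A shift of the 4 wild-type low fat arrays as a group stays open: 71.1% of the shared genes (jackknife SE 9.57) moved the same way with diet in knockout fat, with 660 called the same way and 102 the opposite way there, but the bound of 50% set beforehand was too low, since shifts placed on genes at random gave 53.9% to 58.5% in 100 simulations, over the lower 95% bound of 52.3%. More macrophages as the whole cause were argued against by the fat mass list, of genes made by adipocytes, whose lowest knockout array lay 0.972 above the highest wild-type array (larger SD 0.412), and as the source of the macrophage genes they stay open, since for that list the distance was 0.0848 (larger SD 0.193). The Cre transgene or the breeding of the knockout line and the loss of Sirt1 cannot be told apart, since the design held 0 Cre-carrying arrays with intact Sirt1, and an effect of that loss stays open as a hypothesis.

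Epithelial genes were high in wild-type high fat replicate 4. Of 24 genes on the array from an epithelial list of 25, written for this test before the values of its genes were seen, 13 were at least 4-fold over the highest of the other 15 arrays, and 32 genes of all tested were that far over the others in this array, against 0 or 1 in each other array. More mesothelium was argued against by a median excess of 0.0403 over 5 mesothelial genes (-0.193 to 0.675). Swapped or scaled values as the source of the excess were argued against by genes off the list at its level in the other 3 arrays of the group, of which 1.45% of 8125 reached a log2 of 4 and were that far over the others (upper bound 1.74%), against 54.2% of the list (lower bound 32.8%); a median difference of 0.017 over all genes, the test planned beforehand, decides nothing because GCRMA brings arrays to a common distribution. Epithelium of another organ in that sample, such as the bladder lining, may be the source, as a hypothesis, and the design names no biological difference for that array alone.

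The 361 genes changed the same way by knockout on both diets include Tfr2, Olr1, Pnpla3, Itgax, Adgrg2 and Acsm3. Of 100 tested neighbours of Sirt1, 3 were among them, or 3% against 2.99% elsewhere (one-sided Fisher's exact p = 0.579, odds ratio 1, 0.202 to 3.05), so a strain segment carried with the floxed allele stays open for single genes. Whether it is the source of most of them cannot be decided by the 0.831% that lie near Sirt1 (upper bound 2.41%). The 100 neighbours could not have held most of 361 genes whatever their values. Low signal as the source of most cannot be decided by the 74.5% (69.7% to 78.9%) with a mean log2 of 6 or more. The median of all genes tested was 8.30 or more in every array, so that limit lay well under their middle. The median of the mean log2 of the 361 genes was 7.738, under the 8.37 of the other genes called by knockout on the low fat diet. The percent over all genes tested was not computed. An effect of the genotype stays open as a hypothesis.

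Other splits of the arrays were counted for each comparison. Of the 35 splits of 8 arrays 4 and 4, only the real split, 1 of 35, gave as many genes in each pairwise comparison. For diet in wild type the real split gave 3334 genes and the highest other 0, for diet in knockout 3852 and 1, for knockout on the low fat diet 1292 and 447, and for knockout on the high fat diet 2351 and 1. The split with 447 genes exchanged wild-type low fat replicate 2 and knockout low fat replicate 4. For the interaction the real grouping was 1 of 100, with 1569 genes against a highest other of 572. By the limit of 5% set beforehand, chance was argued against for each of these 5 counts, without adjustment over them. A share of 1 in 35 is the lowest that 35 splits can give. The splits treat the arrays as independent samples. They cannot tell an effect from a shift of a whole group of arrays.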

How the results depend on the processing

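The alternative without the arrays with muscle transcripts was chosen after the data were seen, and the others before the data were examined. No value of a named gene or list was reversed, 0 of 4642 values of 179 named gene results and 0 of 1298 of 59 list results. Many of these values could not reverse. Leaving out an array outside a pairwise comparison, or adding the block, leaves its fold change as it was. Genes picked because their groups did not overlap keep their sign when a single array is left out. The lists were those already called. The lists were not rerun with centring, quantile normalization, array weights or the mean-variance trend. With arrays centred the majority of calls turned from up to down for diet in wild type (57.43% to 44.55% up), diet in knockout (53.56% to 47.28%) and knockout on the low fat diet (61.73% to 47.46%). It stayed up for knockout on the high fat diet (54.18%). For the interaction it turned to positive with quantile normalization (52.77%). Of the gene values 4562 kept their direction and side of the threshold, 73 fell short of it and 7 passed it; of the list values 1154 kept them and 144 fell short. In the order diet in wild type, diet in knockout, knockout on the low fat diet, knockout on the high fat diet, interaction, the counts were 9059, 7071, 4619, 3184 and 2898 with all probe sets, a larger number of units tested, with 3848 calls shared by diet in wild type and knockout on the low fat diet. Without the 5 arrays with muscle transcripts, so with fewer samples, they were 2567, 2341, 845, 814 and 424, with 721 shared. Array weights gave 5354 for diet in knockout, 3424 for knockout on the high fat diet and 2481 for the interaction; the cause was not tested. The 8 arrays compared alone gave 1292 for knockout on the low fat diet, an adjusted p under 0.10 gave 2495 interactions, and a 1.5-fold minimum gave 1277 shared calls. With the control arrays split 2 and 2, 1014 calls were shared and r was 0.6686. With an estimated correlation 0 of 59 list shifts were called.

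With each array left out in turn, the counts ran from 3581 to 4735, 2673 to 3821, 1426 to 3075, 1084 to 2079 and 1098 to 2382, shared calls from 1264 to 2534 and list shifts from 50 to 63. The Sirt1 difference ran from -0.33 to -0.04 on the low fat diet and from -0.29 to -0.07 on the high fat diet. The correlation ran from 0.8003 to 0.8513 for diet in wild type against knockout on the low fat diet, from 0.4853 to 0.5598 for diet in both genotypes and from 0.1158 to 0.2196 for knockout on both diets.

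The numbers do not pair the samples. With the replicate number as a replicate block, 4188, 3400, 2118, 1670 and 1390 genes and 1801 shared calls were called, and Sirt1 differed by -0.19 (adjusted p = 0.499) and -0.22 (adjusted p = 0.449). The block ended the call of Sirt1 with diet in knockout fat (adjusted p = 0.0558). Signal over background limits the 6115 genes under the filter, which were not tested.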

Other observations

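Skeletal muscle transcripts varied between arrays within every group, and the muscle list was called in no comparison (camera adjusted p = 0.564 and 0.426 for diet in wild type and knockout, 0.486 and 0.374 for knockout on the low and high fat diet, 0.843 for the interaction). Its mean ± SD was 6.86 ± 1.83 in wild type and 6.45 ± 1.76 in knockout on the low fat diet, and 6.46 ± 1.32 and 6.06 ± 1.01 on the high fat diet (n = 4 each). Tnnt3, a troponin gene of fast muscle, ran from 3.40 to 10.52 over the 16 arrays. Of the sex-linked genes Xist stood between 11.1 and 11.9 in the 16 arrays, while Kdm5d, Eif2s3y and Uty stood at 2.14 or less. The sex-linked list was not called (camera adjusted p = 0.564, 0.68, 0.282, 0.967 and 0.401 in the same order).

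Endoplasmic reticulum stress genes were called in no comparison (camera adjusted p = 0.878 and 0.163 for diet in wild type and knockout, 0.345 and 0.601 for knockout on the low and high fat diet, 0.182 for the interaction), with 6 of 16 risen and 3 fallen with diet in knockout fat. Neutrophil and mast cell markers were not called either (0.776, 0.864, 0.078, 0.115 and 0.838), though S100a8, a neutrophil alarmin gene, was higher in knockout fat by 2.75 on the low fat diet (adjusted p = 0.000347) and by 2.39 on the high fat diet (adjusted p = 0.0014). Mammary epithelium (0.862, 0.585, 0.79, 0.275 and 0.554) and erythroid markers (0.85, 0.864, 0.79, 0.812 and 0.907) had 1 tested gene each. The sirtuin and NAD list had 0 of 17 genes past the threshold with knockout on the low fat diet (camera adjusted p = 0.468, limma) and 0 for the interaction (0.254).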
